A study of Homo sapiens with 46 samples.

How the data were processed

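Ribosome footprints and mRNA were sequenced from H1, an established human embryonic stem cell line grown without feeder cells, after lentiviral delivery of a control short hairpin RNA (shControl), of one against KBTBD8 (shKBTBD8) or of one against TCOF1 (shTCOF1). Cells were sampled as undifferentiated cells (hES) or after 1, 3 or 6 days of neural conversion in a medium the labels call NIM (ND1, ND3 and ND6). Ribosome footprints are the pieces of mRNA that ribosomes shield from RNase I. Per the labels' protocols, footprint samples were digested with RNase I and ribosomes were pelleted before library preparation.

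The 46 libraries were read as 2 sets, told apart by how their titles are written. The first set holds 32 libraries, with shControl and shKBTBD8 at 4 stages, 2 numbered replicates per group and both assays. The second set holds 14 libraries, 7 per assay, with 2 shControl libraries at hES and 1 library each of shKBTBD8 and shTCOF1 at hES and of shControl, shKBTBD8 and shTCOF1 at ND3. The labels do not say that the sets are separate experiments, nor that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

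The deposited values are whole-number counts, one per transcript row, in files of 63691 rows with the same identifiers in the same order. Each file also has a length for each row, whose unit is not stated. The submitters' processing notes name the hg19 build, CASAVA 1.8, Bowtie2 2.0.6 and TopHat2 2.0.7. The counting program, the handling of reads that map to several places and the strand are not given in the sources used here. Rows of neighbouring isoforms often hold the same reads, so file totals are not depths. Totals as deposited were 34.3 to 57.4 M per mRNA library and 2.31 to 21.1 M per footprint library in the first set. Those of the second set were 24.0 to 62.4 M and 8.80 to 16.4 M.

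Rows with a mean count of at least 10 were therefore grouped. Rows within 20 rows of each other were linked when a chi-square statistic per degree of freedom over the 46 libraries lay below 2, and the row with the highest total stood for its group. This gave 17680 transcript groups, called transcripts from here on. Of these, 7396 held 1 row and the largest held 112. Among 19353 random distant pairs, 2 lay below the limit, against 56.1% of neighbouring pairs. Near-identical gene copies and antisense transcripts could still share reads, and such rows are uncertain. This grouping was chosen after the files were seen.

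The files do not pair the identifiers with gene names, and 0 of them matched the gene tables used here. The 19 gene lists fixed before the data were examined, and the parts of the rule for named genes that need names (KBTBD8, TCOF1, NOLC1 and CUL3, and up to 4 members per list), could therefore not be applied. The rest of that rule takes up to 5 rising and 5 falling genes per main comparison (3 each for hES) and needs no names. It was computed, but its identifiers are not listed, since without names at most 2 rising and 2 falling ones are printed. The level of the targeted genes, which would check the labels, is not reported here. The 4 identifiers printed were chosen after their values were seen. Of these, uc003dmy.3 is also among those the rule takes at hES, and the others lie outside it. Near-identical copies of their sequences were not examined here. In place of the lists, groups of transcripts were defined in one set and tested in the other, which shares no library with it. Whether the sets share cultures or other material is not stated, so the other set may not be an independent test. Transcripts with an adjusted p under 0.05 and a change of at least 1 (log2) between hES and ND3 formed conversion-induced and conversion-repressed groups. In the first set this change was taken in control libraries, and in the second over control and knockdown libraries together. The conversion score of a library is the mean log2 CPM of the induced group less that of the repressed group, with a prior count of 2.

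Counts were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F-test, Benjamini-Hochberg adjustment, threshold 0.05) in R 4.3.3. All 16 libraries of an assay in the first set shared a model of 8 groups. The second set used stage and knockdown as additive terms over 7 libraries, with 3 residual degrees of freedom. A knockdown effect that differs between hES and ND3 counts there as spread, so those p-values also hold such differences. Translational efficiency (TE), the footprint level relative to the mRNA level, was tested as the interaction of assay and group in one model over both assays. Standard errors were derived from the F statistic. Groups were tested with camera from limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, over a family of 72 tests. Scores were compared by an exact two-sided permutation test within stages, which takes the stages as independent. Correlations of fold changes are across transcripts, which are not independent replicates. Where both effects shared controls, 20 simulations of unchanged knockdowns gave a reference, which depends on the fitted spread.

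Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter, the replicate number as a block, only the groups compared, both sets together, only control and 1 knockdown, correlations over means of at least 50 counts, and leaving out each library. Chosen after seeing the data were all distinct rows, a mean count of at least 100, leaving out the footprint libraries with over 15% of transcripts at 0, and effects at single stages.

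On simulated counts with 200 changed transcripts, the mRNA test of shKBTBD8 at ND6 recovered 68% of changes of 1 and 98% of changes of 2 (log2), over 17659 transcripts. For footprints at ND6 the shares were 5% and 38% over 16521 transcripts, and for TE they were 5% and 35% over 17680. For shTCOF1 in the second set they were 65% and 97% in mRNA over 17596 transcripts, with 26 unchanged transcripts also called, and 21% and 53% in footprints over 15613, with 13 called. For TE of shTCOF1 they were 8% and 43% over 17426. The changes simulated for shTCOF1 were the same at hES and ND3, so recovery of a change at 1 stage alone was not measured. Replicates were compared before use. Their counts differed by more than sampling noise in every pair, with a chi-square per degree of freedom of at least 5.78, so none was treated as a duplicate.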

Results

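Ribosome profiling and mRNA sequencing were used to follow H1 human embryonic stem cells through neural conversion, with and without depletion of KBTBD8 or TCOF1. KBTBD8 is a substrate adaptor of the CUL3 ubiquitin ligase, and TCOF1 encodes treacle, a nucleolar protein linked to ribosomal RNA synthesis. The series concerns how ubiquitin-dependent control of translation bears on cell fate. On 1 row per transcript, depth was 16.3 to 27.1 M counts per mRNA library and 1.03 to 10.2 M per footprint library in the first set, and 11.3 to 29.2 M and 4.07 to 7.93 M in the second. In mRNA libraries at most 0.588% of transcripts had no count. In footprint libraries this share reached 21.8% in replicate 2 of shKBTBD8 at both ND3 and ND6 and 16.4% in hES shControl replicate 2 of the second set. Replicates correlated at 0.979 to 0.992 in mRNA and 0.845 to 0.934 in footprints (Pearson's r of log2 CPM across transcripts). Across the sets, hES shControl replicate 1 of each correlated at 0.969 in footprints, above every replicate pair. In mRNA they correlated at 0.983, against 0.979 between the hES shControl replicates of the first set. The sets may therefore share material at hES, which was not tested.

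The first comparison asked how control cells changed during neural conversion. The mRNA of control cells changed broadly, and by more transcripts at each later day. After 1 day 2364 transcripts were higher and 2396 lower than at hES, after 3 days 4181 and 4202, and after 6 days 5252 and 5200, of 17659 tested (edgeR quasi-likelihood test, adjusted p under 0.05, n = 2 per group). The median change among those called at ND6 was 1.06 for the higher and -0.94 for the lower transcripts (log2), and 1012 rose and 752 fell by at least 4-fold. Leaving out replicate 1 or 2 of the ND1 control reduced the ND1 count from 4760 to 2429 or 2833.

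Footprints moved with the mRNA. Of the transcripts that rose in mRNA at ND6 and were tested in footprints, 4384 of 4888 (89.7%) had a positive footprint change, and of those that fell, 4572 of 5002 (91.4%) had a negative one. Among those that rose in mRNA, 129 had a footprint fall that itself passed the test (edgeR, adjusted p under 0.05). In footprints alone 180 transcripts rose and 86 fell at ND1, 553 and 626 at ND3, and 1058 and 1469 at ND6, of 16740 tested. These counts depended on single libraries. Without hES control replicate 1 they were 166, 488 and 1179 in total. Without replicate 1 or 2 of the day compared they were 137 or 131 at ND1 and 1445 or 1385 at ND6, at ND3 without replicate 1 665, and without hES control replicate 2 they were 151 at ND1 and 708 at ND3.

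**Figure D1:**
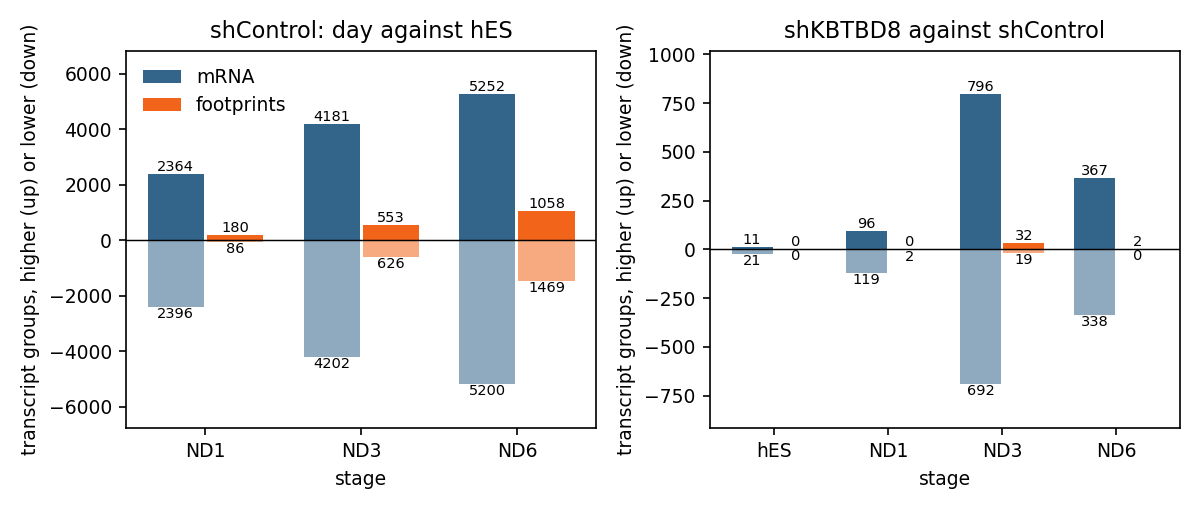
Transcripts called higher (bars above 0) or lower (paler bars below 0) in mRNA and footprints of the first set, by stage, for control cells against hES on the left and shKBTBD8 against shControl on the right (edgeR, adjusted p under 0.05, n = 2 per group). In control cells mRNA calls reach 5252 higher and 5200 lower at ND6, and in shKBTBD8 they are most numerous at ND3, at 796 and 692.

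A group of abundant transcripts lost ribosome footprints relative to mRNA during conversion. At ND6, TE was lower than at hES for 221 transcripts and higher for 9, of 17680 tested (edgeR interaction test, adjusted p under 0.05). By DESeq2, TE was lower for 295 and higher for 50. The 221 had a median TE change of -2.01 (log2), a median mRNA change of 0.48 and a median footprint change of -1.44. Their median length value was 164, against 390 for all tested transcripts, and their median abundance was 9.19 log2 CPM against 4.16. In the second set, with control and knockdown libraries fitted together, TE was lower at ND3 than at hES for 233 transcripts and higher for 24. Of the lower transcripts, 183 were in both lists, against 2.91 for independent lists. That 2.91 takes every tested transcript as equally likely to be called, while both lists hold abundant ones (medians 9.19 and 9.40 log2 CPM). It also takes the sets as independent, which the labels do not state. For the 233 transcripts the median log2 ratio of footprint to mRNA CPM in the first set was -0.13 and -0.83 in the control hES replicates, -0.98 and -1.03 at ND1, -1.56 and -1.60 at ND3, and -2.30 and -2.51 at ND6. Their decrease at ND6 passed camera with an estimated correlation (adjusted p = 0.00115) and fry (adjusted p = 0.000488). Without hES control replicate 1 of the footprints the TE calls at ND6 were 125 rather than 230, without footprint ND6 replicate 2 they were 149, and without mRNA hES replicate 1 or 2 they were 152 or 153.

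**Figure D2:**
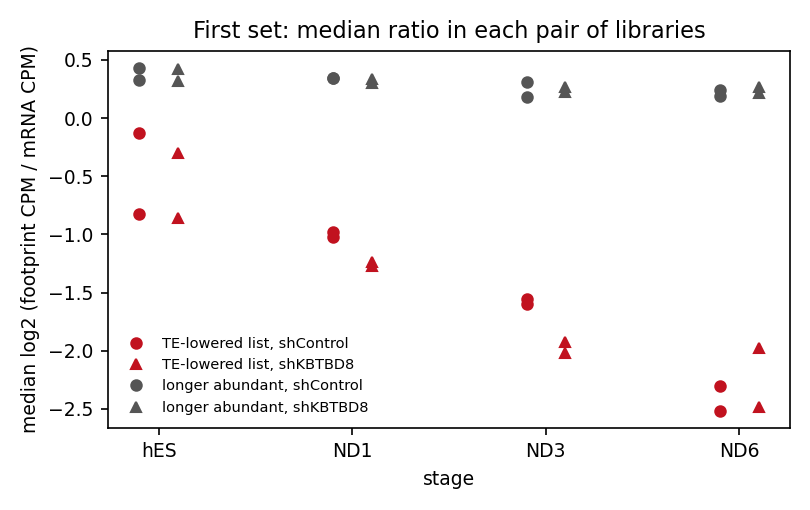
Median log2 ratio of footprint CPM to mRNA CPM in the first set, by stage, for the 233 transcripts with lower TE in the second set (red) and for abundant transcripts of greater length (grey). Each point pairs a footprint with an mRNA library of the same group and number, circles are shControl and triangles shKBTBD8. In control cells the red points lie at -0.13 and -0.83 at hES and at -2.30 and -2.51 at ND6.

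The second comparison asked what the hairpin against KBTBD8 changed at each stage. The levels of KBTBD8 and TCOF1 themselves were not analysed here, since the files do not pair identifiers with gene names. In mRNA, few transcripts passed the test in undifferentiated cells and many did at ND3. The effect at ND3 was not itself tested against that at hES. At hES 11 transcripts rose and 21 fell, at ND1 96 and 119, at ND3 796 and 692, and at ND6 367 and 338, of 17659 tested (edgeR, adjusted p under 0.05, n = 2 per group). The median size among calls at ND3 was 1.14 for rises and -0.92 for falls (log2). The lists at ND3 and ND6, which share no library, held 167 rising and 145 falling transcripts in common, against 16.5 and 13.2 for independent lists. Those 2 values take every tested transcript as equally likely to be called. Both tests also used the same fitted spread for each transcript, so the lists are not fully independent. With only the groups compared 0 passed at hES, and with both sets together the balance there turned to 23 higher and 9 lower. At ND6 the balance turned to 75 higher and 101 lower without control replicate 1, to 180 and 204 without control replicate 2, and to 191 and 200 with only the groups compared. Counts depended on single libraries. At hES they were 14 or 17 without control replicate 1 or 2 and 9 or 11 without shKBTBD8 replicate 1 or 2. At ND1 they were 36 or 55 without control replicate 1 or 2 and 55 or 64 without shKBTBD8 replicate 1 or 2. At ND3 they were 601 without control replicate 1 and 648 or 676 without shKBTBD8 replicate 1 or 2, and at ND6 176 or 384 without control replicate 1 or 2 and 362 without shKBTBD8 replicate 2.

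The transcript uc003dmy.3 fell under shKBTBD8 in mRNA at hES, from 16.3 ± 4.17 to 3.48 ± 0.01 CPM (SD, n = 2 each), a log2 change of -2.23 ± 0.24 (SE; edgeR adjusted p = 0.00108). It also fell at ND1 and ND3, with log2 changes of -2.29 and -1.23 (edgeR adjusted p = 0.000484 and 0.00759). At ND6 its change was -0.91 ± 0.30 (SE; edgeR adjusted p = 0.115). The call at ND3 was lost without control replicate 1 or shKBTBD8 replicate 1, where the change was -1.12 or -1.08, and that at hES when only its 4 libraries were fitted (-2.24). Its mRNA level in the second set was 10.2 CPM in shKBTBD8 and 16.8 ± 0.37 (SD, n = 2) in control cells at hES, and 4.48 against 7.93 CPM at ND3. Over both stages the change was -0.82 ± 0.14 (log2, SE; edgeR adjusted p = 0.137), which did not pass, though it did by DESeq2 (-0.83). Transcripts uc021sgb.1 and uc001ywu.3 were among 5 that rose at all 4 stages of the first set. Their length values were 224 and 52, and their mRNA changes lay close together, as at ND1 (1.22 and 1.21). Whether they are independent was not tested. At hES uc021sgb.1 rose by 1.02 ± 0.15 (log2, SE; edgeR adjusted p = 0.00896), from 315.0 ± 2.83 to 641.1 ± 5.37 CPM (SD, n = 2 each), and uc001ywu.3 by 0.95 ± 0.14 (edgeR adjusted p = 0.00801). Their mRNA changes under shKBTBD8 in the second set were 0.01 ± 0.09 and 0.02 ± 0.09 (SE; edgeR adjusted p = 0.977 and 0.965). Their calls in the first set depended on single libraries. At hES the calls were lost without control replicate 1 or 2 or shKBTBD8 replicate 1, with changes of 1.06, 0.98 and 1.00 for uc021sgb.1 and 0.96, 0.93 and 0.90 for uc001ywu.3, and uc021sgb.1 also without shKBTBD8 replicate 2 (1.05). At ND6 both were lost without control replicate 1 (0.76 and 0.74) and uc021sgb.1 without shKBTBD8 replicate 2 (0.64). With both sets fitted together neither passed at hES (0.65 and 0.60) or ND3 (0.74 and 0.69). With only the groups compared neither passed at hES (1.01 and 0.94), nor uc021sgb.1 at ND6 (0.88).

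Conversion-induced transcripts tended to be lower and conversion-repressed transcripts higher in shKBTBD8 cells of the first set. Among 1533 conversion-repressed transcripts, defined in the second set, 297 rose and 34 fell at ND3, with a median change of 0.34 (log2). Among 1785 tested conversion-induced transcripts 87 rose and 234 fell, with a median of -0.11. Both groups passed camera at ND3 (adjusted p = 2.79e-13 and 0.000695). With an estimated correlation neither did (adjusted p = 0.0618 and adjusted p = 0.980), while fry gave 0.00138 and 0.647. The conversion score was lower in both shKBTBD8 replicates than in both control replicates at each of the 4 stages in mRNA. It was 1.49 ± 0.01 in control and 0.87 ± 0.03 in shKBTBD8 cells at ND3 (SD, n = 2 each). Over the 4 stages the mean difference was -0.37 in mRNA (exact permutation test, two-sided p = 0.00154, the smallest it can give) and -0.25 in footprints (exact permutation test, two-sided p = 0.00309). That test shuffled labels within each stage, as if the stages were independent. If they came from the same transduced cells, which the labels do not say, these p-values are too small. Differences between numbered replicates correlated between groups at up to 0.811 in mRNA (median 0.242). The footprint difference did not pass among transcripts with a mean count of at least 100 (-0.20; exact permutation test, two-sided p = 0.0710).

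**Figure D3:**
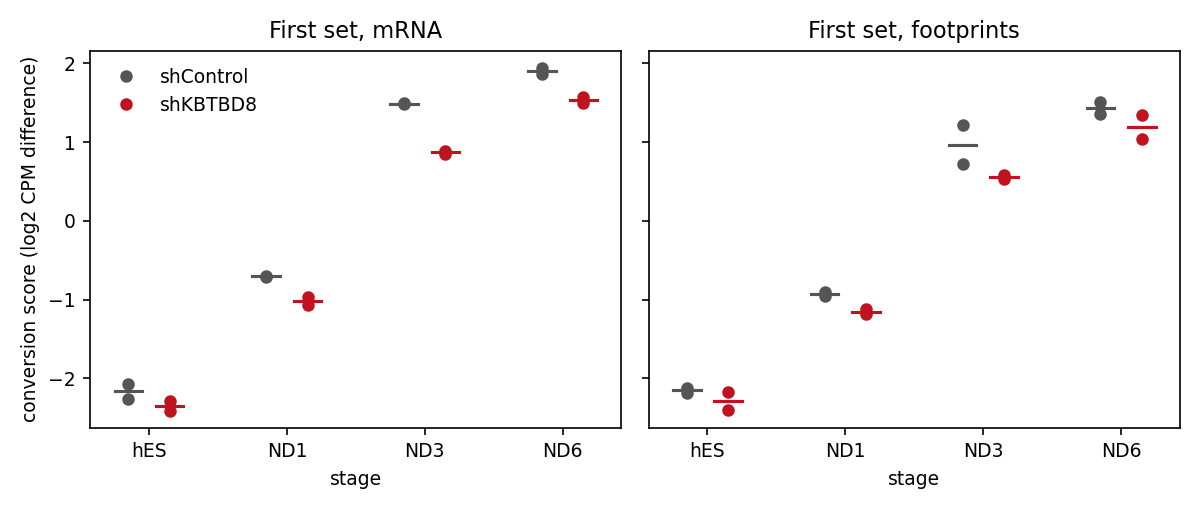
Conversion score of each library in the first set (points) and mean of each group (lines), by stage, for mRNA on the left and footprints on the right. The score is the mean log2 CPM of conversion-induced less that of conversion-repressed transcripts, both defined in the second set. At ND3 the mRNA scores are at least 1.48 in shControl and at most 0.89 in shKBTBD8.

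Footprints followed the mRNA changes, and no TE change passed the test. Of the transcripts that rose in mRNA at ND3 under shKBTBD8, 664 of 756 tested in footprints (87.8%) had a positive footprint change, and of those that fell 610 of 671 (90.9%) had a negative one. In footprints alone 0 transcripts passed at hES (edgeR; 200 at an unadjusted p under 0.05; 1 by DESeq2), 2 fell at ND1, 32 rose and 19 fell at ND3, and 2 rose at ND6, of 16740 tested. For TE 0 transcripts passed at hES, ND1, ND3 or ND6 (edgeR; 175, 241, 661 and 403 at an unadjusted p under 0.05; 1, 3, 1 and 0 by DESeq2), of 17680 tested. These counts at an unadjusted p under 0.05 all lie below a share of 0.05 of the transcripts tested. Exact tests of unchanged transcripts would give about that share, so these tests were conservative. Simulated TE changes of 2 (log2) were recovered in 35% of cases at ND6, so smaller changes were mostly not detectable with these libraries. Leaving out replicate 1 of shKBTBD8, so that the sparse replicate 2 stood alone, gave 1031 footprint and 1992 TE calls at ND3 and 243 and 633 at ND6, and turned the footprint balance to 145 higher and 886 lower at ND3 and 36 and 207 at ND6. Without control replicate 2 the footprint count at ND3 was 105, and without shKBTBD8 replicate 2 it was 18. The 2 footprint calls at ND1 became 0 without control replicate 1 or either shKBTBD8 replicate, and the 2 at ND6 became 1 without either control replicate or shKBTBD8 replicate 2. At hES, leaving out footprint shKBTBD8 replicate 1 gave 2 footprint and 51 TE calls, and at ND6 leaving out footprint control replicate 1 gave 4 TE calls.

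In the second set the mRNA effect of shKBTBD8 differed from that in the first for 44 transcripts at hES and 286 at ND3, of 17665 tested (edgeR test of the difference, adjusted p under 0.05). That set has 1 shKBTBD8 library per stage and 1 control library at ND3, so the spread came from other groups, and the lone libraries were assumed to vary like them. In the test over both stages that follows, an effect that differed between hES and ND3 counted as spread. Over both stages 3 transcripts rose and 1 fell in mRNA, of 17616 tested, 0 passed in footprints (edgeR; 717 at an unadjusted p under 0.05; 21 by DESeq2) and 0 in TE (edgeR; 857 at an unadjusted p under 0.05; 28 by DESeq2). The conversion score, here from groups defined in the first set, was -1.82 in shKBTBD8 and -2.52 and -2.46 in control mRNA libraries at hES, and 1.01 against 1.06 at ND3. With 1 library per knockdown and stage, these scores have no replicate check. Over both stages together, conversion-induced transcripts had a median of 0.21 (log2) under shKBTBD8 and passed camera (adjusted p = 5.77e-14), though not with an estimated correlation (camera adjusted p = 0.655). That sign was opposite to the first set. The scores differed in that direction at hES alone, and at ND3 shKBTBD8 lay below control as in the first set. Without the hES or the ND3 shKBTBD8 library the mRNA count was 95 (36 higher and 59 lower) or 138 rather than 4, and the footprint count 1 or 16 rather than 0.

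The third comparison asked whether the hairpin against TCOF1 gave a profile like that of KBTBD8. The model of the second set took each knockdown effect to be the same at hES and ND3, so a change at 1 stage alone was not tested. A difference between the stages counted as spread and could hide calls. From single libraries, mRNA effects at hES and ND3 correlated at 0.10 for shTCOF1 and 0.13 for shKBTBD8, over 15479 transcripts. No transcript passed under shTCOF1 in mRNA (edgeR; 939 at an unadjusted p under 0.05; 22 by DESeq2), footprints (edgeR; 282 at an unadjusted p under 0.05; 5 by DESeq2) or TE (edgeR; 528 at an unadjusted p under 0.05; 1 by DESeq2). Without the hES or the ND3 shKBTBD8 library the mRNA count was 10. For footprints and TE, the shTCOF1 counts at an unadjusted p under 0.05 lie below a share of 0.05 of the transcripts tested. The smallest p in both assays belonged to uc003lry.3, with a change of -0.90 ± 0.09 in mRNA and -1.47 ± 0.20 in footprints (log2, SE; edgeR adjusted p = 0.0766 and 0.216). Its mRNA level was 94.1 CPM in shTCOF1 and 181.3 ± 3.60 (SD, n = 2) in control cells at hES, and 86.4 against 153.7 CPM at ND3. Its mRNA change passed by DESeq2 (-0.90), without the hES or ND3 shKBTBD8 library (-0.92 or -0.91) and with only control and shTCOF1 libraries (-0.91), and its footprint change by DESeq2 (-1.49) and with no filter (-1.46). The changes of uc021sgb.1 and uc001ywu.3 under shTCOF1 were 0.73 ± 0.09 and 0.68 ± 0.09 (log2, SE; edgeR adjusted p = 0.113 and 0.132). Both passed by DESeq2 (0.73 and 0.67), and uc021sgb.1 without the hES or ND3 shKBTBD8 library (0.72 in each) and with only control and shTCOF1 libraries (0.72).

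Across transcripts, the mRNA effect of shTCOF1 in the second set correlated with that of shKBTBD8 at ND3 in the first (Pearson's r = 0.44 over 17612 transcripts), with no library in common. Taken at ND3 alone, from single libraries of the second set and transcripts with a mean of at least 50 counts in each set, r was 0.61 over 15479 transcripts, and it was 0.14 for shKBTBD8 of the second set. The largest r with a difference between replicates of the first set was 0.12 in size for that shTCOF1 effect and 0.15 for that of shKBTBD8, above its 0.14. At hES the shTCOF1 effect correlated with that of shKBTBD8 in the first set at 0.25, close to its largest r with a difference between replicates, 0.23 in size. Transcripts raised by shKBTBD8 at ND3 in the first set had a median of 0.21 under shTCOF1, and those lowered a median of -0.20 (log2; camera adjusted p = 9.93e-21 and 1.66e-21; adjusted p = 0.700 for both with an estimated correlation). Over hES and ND3 together, the conversion groups defined in the first set did not pass under shTCOF1, with a median of 0.01 for induced and 0.01 for repressed transcripts (log2; camera adjusted p = 0.797 and 0.322). The mRNA conversion score was -2.44 in shTCOF1 at hES, against -2.52 and -2.46 in control. At ND3 it was 0.90 against 1.06, and in footprints 0.51 against 0.73, lower as for shKBTBD8 of the first set. These scores come from single libraries at ND3, and ND3 was not tested alone. In footprints r was 0.09 over 16161 transcripts. At ND3 alone, with the same filter, it was 0.16 over 10141 transcripts, against a largest r of 0.035 in size with a difference between replicates. With the control changes of both sets from hES to ND3 regressed out it was 0.30, for which no such reference was computed. For shKBTBD8 of the second set, the footprint r at ND3 was 0.046, under its largest r with a replicate difference (0.050 in size). With the control changes regressed out it was 0.14.

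**Figure D4:**
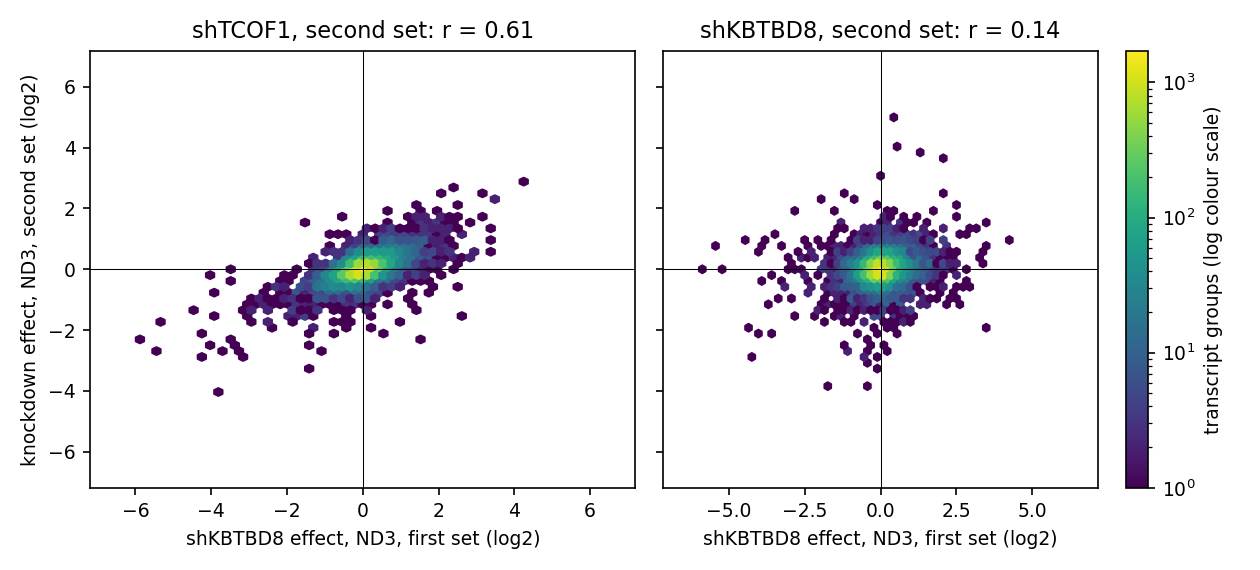
Change in mRNA at ND3 in the second set (vertical axis, log2, 1 library per knockdown and 1 control library) against the shKBTBD8 effect at ND3 in the first set (horizontal axis, log2, n = 2 per group), for 15479 transcripts, with colour giving their number per hexagon. The r across transcripts is 0.61 for shTCOF1 on the left and 0.14 for shKBTBD8 on the right.

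Within the second set, both knockdowns shared controls. Their mRNA effects correlated at 0.11 with a covariance of 0.00933, below the means of 0.43 and 0.0255 of simulated unchanged knockdowns. That r lay below every simulation (0.41 to 0.46). Whether the simulated spread was too large was not tested, so the simulations are not taken as chance values. In footprints r was 0.44 and the covariance 0.419, against means of 0.38 and 0.423 in simulation, where r ranged from 0.35 to 0.41. Among transcripts with a mean of at least 50 counts r was 0.47 and the covariance 0.0873, against 0.41 (highest 0.43) and 0.0835 (highest 0.0891) in simulation. With 2 control libraries at hES and 1 at ND3 the controls were not split, and no shared effect is read from these values. Directly compared, 7 transcripts were higher and 17 lower in shTCOF1 than in shKBTBD8 mRNA (edgeR, adjusted p under 0.05), and 0 differed in footprints (edgeR; 504 at an unadjusted p under 0.05; 15 by DESeq2). The mRNA count of 24 became 11 without hES control replicate 1, 190 or 12 without the hES shKBTBD8 or shTCOF1 library, and 12, 179 or 0 without the ND3 control, shKBTBD8 or shTCOF1 library. In footprints, leaving out hES control replicate 1 or 2 gave 2 or 3, and leaving out the ND3 shKBTBD8 library 14.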

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

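The differences between the sets and the tests of swapped labels, library depth and an off-target effect were chosen only after the results were seen, while the test of conversion progress was written before its result.

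The effect of shKBTBD8 differed between ND6 and hES for 153 transcripts in mRNA, 75 higher and 78 lower at ND6 (edgeR interaction test, adjusted p under 0.05). That near-even balance turned under several settings, as to 110 higher and 58 lower without hES control replicate 1. The mRNA count was 35 without ND6 control replicate 1 and 95 or 84 without hES shKBTBD8 replicate 1 or 2. In footprints it differed for 2 transcripts. That count was 22 (2 higher and 20 lower) without ND6 shKBTBD8 replicate 1, 0 without hES control replicate 1 or ND6 control replicate 2, and 1 without hES control replicate 2, ND6 control replicate 1, either hES shKBTBD8 replicate or ND6 shKBTBD8 replicate 2.

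The effect of shKBTBD8 also differed between the sets. In mRNA it did so for 44 transcripts at hES and 286 at ND3 of 17665 tested, and in footprints for 3 at hES and 17 at ND3 of 17436 tested (edgeR, adjusted p under 0.05). The second set has 1 shKBTBD8 library per stage and 1 control library at ND3, so the spread came from other groups, and these lone libraries were assumed to vary like them.

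At ND3 the mRNA effect of shKBTBD8 in the second set was unlike that in the first. An exchange of the shKBTBD8 and shTCOF1 labels at ND3 alone is argued against. Of the 100 transcripts that differed most between them at hES, 74 percent kept their sign at ND3. An exchange at both stages would keep the sign too, was not tested and stays open. In r with the first set's shKBTBD8 effect, shTCOF1 lay higher (0.25 at hES and 0.61 at ND3). But mRNA of uc003dmy.3 was below control in the libraries labelled shKBTBD8 in both sets, and not in those labelled shTCOF1. uc003lry.3 changed by -0.90 (log2) under shTCOF1, but by 0.00 at hES and 0.10 at ND3 under shKBTBD8 of the first set. uc021sgb.1 and uc001ywu.3 went the other way. They rose by 1.02 and 0.95 under shKBTBD8 of the first set at hES. In the second set they changed by 0.01 and 0.02 under shKBTBD8 and by 0.73 and 0.68 under shTCOF1. These picked transcripts do not decide it. A shallow library is argued against by its 29.2 M counts, and different progress of conversion by an r of 0.158 once the control change was regressed out. A different off-target or clonal effect stays open, since the second set's effects at hES and ND3 correlated at 0.129, against -0.0041 and 0.141 with the first set's effects at those stages, and single libraries do not decide it. The level of KBTBD8, which would show whether the hairpin worked in each library, was not analysed here.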

How the results depend on the processing

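The settings with all distinct transcripts, a mean count of at least 100 and without sparse libraries were chosen only after seeing the data. The conversion scores and fold-change correlations kept their sign under the settings run, and with DESeq2 size factors the 35 results stayed within 1.5 times or on their side of the threshold. The 2 footprint calls of shKBTBD8 at ND6 became 2 higher and 1 lower there. The balance of higher and lower calls turned under some settings, and only examples are given. Control footprints at ND3 turned from 553 and 626 to 648 and 506 with only the groups compared, and near-even control mRNA balances turned, as at ND6 to 5205 and 5247 with DESeq2 size factors. Alternatives fixed for normalised values (pseudocounts, a filter on units, fold changes of scaled values) were not run, since the deposited values were counts. The cause of the differences below was not tested, except that all distinct transcripts count isoforms of 1 group repeatedly and left-out libraries leave fewer samples. A group left with 1 library was assumed to vary like the others. Footprint libraries were shallower and varied more than mRNA libraries (biological coefficient of variation 0.375 against 0.137), and which of these limits the footprint and TE counts was not tested.

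By the DESeq2 Wald test, footprint calls at ND1 in control cells were 457. For shKBTBD8, mRNA calls were 119 at hES and 458 at ND1, footprint calls 1, 26, 121 and 45 at hES, ND1, ND3 and ND6, and TE calls 1, 3 and 1 at hES, ND1 and ND3. The ND6 to hES difference had 318 in mRNA and 4 in footprints. In the second set they were 123, 21 and 28 for shKBTBD8 in mRNA, footprints and TE, 22, 5 and 1 for shTCOF1, and 256 and 15 between both in mRNA and footprints.

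With all distinct transcripts, control mRNA calls were 10672, 19021 and 23191 at ND1, ND3 and ND6 and footprint calls 647, 2617 and 5246. For shKBTBD8 they were 58, 572, 3767 and 1803 in mRNA at hES, ND1, ND3 and ND6, 4 and 99 in footprints at ND1 and ND3, and 365 for the mRNA difference between ND6 and hES. In the second set mRNA calls were 11 for shKBTBD8 and 92 between the knockdowns.

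With only the groups compared, control footprint calls were 744 at ND1 and 4000 at ND6. For shKBTBD8, mRNA calls were 0, 338 and 391 at hES, ND1 and ND6, footprint calls 46, 1 and 1 at ND1, ND3 and ND6, and the ND6 to hES difference 31 in mRNA and 0 in footprints. With only control and 1 knockdown, mRNA calls for shTCOF1 were 10. With both sets together, shKBTBD8 calls were 730 in mRNA at ND3 and 3 and 21 in footprints at hES and ND3. With no filter, footprint calls were 5 for shKBTBD8 at ND6 and 2, 1 and 3 in the second set for shKBTBD8, shTCOF1 and their difference. With a mean count of at least 100, footprint calls were 11 for shKBTBD8 at ND6, the knockdowns of the second set differed by 14 in mRNA and 3 in footprints, and the footprint score difference was -0.20 (exact permutation test, two-sided p = 0.0710), no longer past the threshold. Without sparse libraries, footprint calls were 427 at ND1 in control cells, 17, 27 and 1 for shKBTBD8 at ND1, ND3 and ND6, 1 for the ND6 to hES difference and 3 between the knockdowns.

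With the replicate number as a block (replicate block), shKBTBD8 calls were 103, 574, 2503 and 1286 in mRNA at hES, ND1, ND3 and ND6, 10 and 17 in footprints at ND1 and ND6, and 329 for the mRNA difference between ND6 and hES. With footprint and mRNA libraries of the same group and number as a block, TE calls at ND6 in control cells were 227, though the labels name no culture and differences between numbers correlated across assays at only -0.214 to 0.474 (median 0.0991). The numbers did not pair the samples throughout, since differences between numbered replicates correlated between groups at -0.0715 to 0.811 in mRNA (median 0.242) and -0.156 to 0.430 in footprints (median 0.0904).

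Without 1 library at a time, control mRNA calls ranged from 2429 to 4162 at ND1, footprint calls from 131 to 166 at ND1, 488 to 1214 at ND3 and 1179 to 1688 at ND6, and TE calls at ND6 from 125 to 276. For shKBTBD8, mRNA calls ranged from 9 to 17 at hES, 36 to 64 at ND1, 601 to 1703 at ND3 and 176 to 601 at ND6, and footprint calls from 0 to 2, 0 to 3, 18 to 1031 and 1 to 243. TE calls ranged from 0 to 51 at hES, 0 to 1992 at ND3 and 0 to 633 at ND6, and the ND6 to hES difference from 35 to 168 in mRNA and 0 to 22 in footprints. Second-set counts ranged from 3 to 138 in mRNA and 0 to 16 in footprints for shKBTBD8, 0 to 10 in mRNA for shTCOF1, and 0 to 190 in mRNA and 0 to 14 in footprints between them.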

Other observations

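The tests on the transcripts with lower TE themselves and on all short abundant transcripts were chosen only after the result was seen, while the tests on class medians and on the footprint calls at ND3 were written before.

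Transcripts with lower TE at ND6 were frequent among short, abundant ones. Of 470 transcripts with a length value of at most 207 (the shortest 25%) and an abundance in the top 10%, 129 (27.4%) had lower TE, against 64 of 1298 longer abundant ones (4.93%; Fisher's exact test, two-sided p = 7.7e-36, over transcripts, which are not independent). The short abundant transcripts as a group passed camera at the preset correlation (adjusted p = 5.84e-25), as did the longer abundant ones (camera adjusted p = 0.000229). The short ones did not pass camera with an estimated correlation (adjusted p = 0.352) or fry (adjusted p = 0.157). In shKBTBD8 cells the median ratio of the transcripts with lower TE in the second set was -0.30 and -0.86 at hES, -1.24 and -1.27 at ND1, -1.93 and -2.02 at ND3, and -1.98 and -2.48 at ND6 (log2). At ND1 and ND3 both lay below both control values (-0.98 and -1.03, and -1.56 and -1.60). The TE of this list under shKBTBD8 had a median of -0.22 at ND1, -0.35 at ND3 and 0.19 at ND6 (log2; camera adjusted p = 2.54e-09, 0.000192 and 6.1e-06). With an estimated correlation none passed (adjusted p = 0.980, adjusted p = 0.985 and adjusted p = 0.980). Under shKBTBD8 of the second set, over hES and ND3 together, the 221 transcripts with lower TE in the first set had a median TE change of 0.01 (log2; camera adjusted p = 0.943). That set has no ND1 libraries and ND3 was not tested alone.

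For the lower TE of 221 transcripts at ND6, the tests written before compared the medians of short and longer abundant transcripts, which differed by 0.015 (log2), by 0.0080 after thinning and by 0.044 in the second set. The values 0.015 and 0.044 are what scaling and a feature of the first set alone predicted, but most of the class did not move, so these medians say little about the 221. On the 221 themselves, the median was -1.17 in the second set. That is against a feature of the first set alone only if the sets are independent, which the labels do not state. It was -1.99 after thinning footprints to 2.44 M. Thinning keeps expected proportions and could hardly move the median of such abundant transcripts, so it does not decide on depth. All short abundant transcripts had a median of -0.069. The 221 were chosen for low TE and were more abundant than that class (median 9.19 against 7.97 log2 CPM), so this does not decide on length and abundance. The median of all transcripts (0.039) says nothing of scaling, since normalisation centres it, but the list defined in the second set had -1.93 at ND6 and longer abundant transcripts of the same libraries -0.084, a gap that 1 factor per library cannot give. A change in translation may underlie it as a hypothesis, but the kind of RNA, its digestion and its recovery were not tested, and the control hES replicates differed (-0.13 and -0.83 for the second set's list).

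Leaving out footprint replicate 1 of shKBTBD8 at ND3 gave 1031 calls, 145 higher and 886 lower. Many transcripts without counts in the remaining library may account for part of this, since 53.3% of the lower calls had 0 counts there, against 19.6% of all tested, though lower calls are chosen for low values there, which raises that share under any explanation. The share of calls with the same sign in replicate 1 was 71.9% (96.6% of the higher and 67.8% of the lower), but both comparisons use the same controls, which raises this share with no effect, and its value without one was not computed, so it does not bear on an effect of the hairpin, which was left undecided.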
